A study of Mus musculus with 12 samples.

How the data were processed

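RNA was measured in primary mouse vascular smooth muscle cells labelled as from wild-type and TIGAR knockout mice, with and without the growth factor PDGF-BB at 40 µg/L for 6 h. Each of the 4 groups held 3 libraries, 12 in all. Per the labels' protocols, cells of passages 4 to 6 came from mice of 4 to 6 weeks of age, and total RNA went into stranded poly(A) libraries. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples. The numbers in the sample names were not used as pairs.

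Per the submitters' processing notes, reads were aligned with HISAT2 and counted with HTSeq on mm10, with no versions given and no strand setting for the counting. Per the file headers, the assembly was GRCm38.p6. The deposited values are CPM (reads scaled to a library sum of 1000000), although the table is named for FPKM. Each library's values summed to 1000000, and 100% of the values were whole numbers of reads within 0.001 read after multiplication by the library's total, with no division by gene length. The table held 55487 genes, of which 25008 were at 0 in all libraries. Reads were recovered from these values, and library totals ranged from 14953807 to 21698488 reads. At the lowest depth 1 read corresponded to 0.0669 CPM.

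Genes were kept when CPM was at least 1 in at least 3 of the 12 libraries, which left 14202 genes. The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(CPM + 1), with 1 mean per group in a single fit of all libraries. Contrasts were PDGF-BB against untreated within each genotype, labelled knockout against wild-type within each treatment, and the interaction, which is the response in labelled knockout minus the response in wild-type. All tests were 2-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05 on the adjusted p. Fold changes are computed on CPM + 1 and so are smaller than ratios of CPM for genes of few reads. Errors beside log2 changes are standard errors (SE) from the same fit, and errors beside CPM are standard deviations (SD) over 3 libraries.

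The design fixed 30 gene lists: smooth muscle contractile genes, matrix and synthetic-state genes, growth factor early genes, PDGF ligands and receptors, glycolysis, pentose phosphate and NADPH supply, NRF2 targets, p53 targets, G1/S genes, G2/M genes, cholesterol synthesis, ATF4 targets, ribosome biogenesis, inflammatory genes, interferon-stimulated genes, TGF-beta and YAP targets, matrix remodelling, osteochondrogenic genes, hypoxia targets, respiratory chain genes, autophagy and lysosome genes, genes near Tigar on the chromosome, sex-linked genes, and markers of endothelial cells, macrophages, fibroblasts, Schwann cells, adipocytes, epithelium and striated muscle. Of these, 29 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of each contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were the alternatives.

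Genes are named by a rule: for each pairwise contrast, the 12 largest rises and 12 largest falls among called genes whose 3 against 3 libraries did not overlap, with a mean CPM of at least 1 and a symbol that is not a predicted gene model. For the interaction these were the 6 most positive and 6 most negative called genes. Up to 4 called members per list and contrast, those with the largest change, serve as examples. Tigar is always given. Some of the genes that the rule names are not reported here.

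The size of the response was compared over genes called in the mean PDGF-BB effect of both genotypes, as the median over genes of the labelled knockout response minus the wild-type response, each taken in the direction of the mean effect. Alternatives changed the pseudocount, filter, scaling (TMM-style and quantile), variance model, library weights, groups in the fit, block and tool (edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads), and left out each library in turn. The groups, contrasts, tests, thresholds, lists, naming rule and these alternatives were chosen before the data were examined. The design file called the unit FPKM, and the same steps were applied to the CPM found. It also named edgeR with TMM scaling as the main test if the table held raw counts. The table held CPM, so limma-trend stayed the main test, and edgeR on recovered reads is an alternative. Removal of the trend with exon length was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

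The procedure was tested on simulated data with 3 libraries per group. In a pairwise contrast limma-trend recovered 64.0% of genes changed 1.5-fold, 86.8% of those changed 2-fold and 98.2% of those changed 4-fold, and 12 of its 175 calls were false. For the interaction it recovered 24.0%, 72.1% and 98.2%, and 8 of its 131 calls were false. Only 75 genes were changed 1.5-fold, 68 2-fold and 57 4-fold, and none of them was of the lowest expression. No simulated library was made to stand apart or to carry a trend with exon length. In the data 8431 of 14202 genes were called for PDGF-BB in wild-type, so these shares do not carry over to such contrasts. Camera recovered 20 of 20 lists shifted 1.3-fold. Simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together. In the data the estimated correlation was 0.776 for G2/M genes, against the preset 0.01.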

Results

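Poly(A) RNA was sequenced from 12 libraries of cultured primary vascular smooth muscle cells of the mouse. The study was set up to compare expression in wild-type and TIGAR knockout cells stimulated with PDGF-BB, a growth factor for smooth muscle. TIGAR is a fructose bisphosphatase under p53 control that limits glycolysis. The 4 groups were wild-type untreated, wild-type with PDGF-BB, labelled knockout untreated and labelled knockout with PDGF-BB, with 3 libraries each. Library totals were 15868736, 19639729 and 16785198 reads for wild-type untreated, 16465545, 15045270 and 16311476 for wild-type with PDGF-BB, 15282415, 14953807 and 17982497 for labelled knockout untreated, and 21698488, 20560511 and 16007290 for labelled knockout with PDGF-BB.

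The libraries separated by treatment and by genotype label. The first principal component held 49.5% of the variance and parted treated from untreated libraries, and the second held 34.4% and parted the genotype labels. Replicate 1 of wild-type with PDGF-BB lay apart from the other 2 libraries of its group, at a root mean square log2 distance of 0.416, against 0.143 to 0.293 for the other 11 libraries. Its log2 difference from replicates 2 and 3 fell with exon length across genes (Spearman rho -0.55 and -0.57), while that of replicate 2 from replicate 3 had a rho of -0.25. Between libraries of the other groups this rho lay between -0.21 and 0.25. Genes are not independent replicates in these correlations.

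Tigar itself was not lower in the libraries labelled knockout. Tigar (ENSMUSG00000038028, chromosome 6, 127085116 to 127109557 in GRCm38) stood at 7.50 ± 0.955 CPM (SD, n = 3) in wild-type untreated cells and at 11.2 ± 1.12 CPM in labelled knockout untreated cells. With PDGF-BB it stood at 11.9 ± 0.659 CPM and 15.2 ± 0.888 CPM. The fewest Tigar reads in any library were 111, in a wild-type one. The labelled knockout against wild-type difference was 0.52 on the log2 scale without PDGF-BB (SE 0.11, adjusted p = 0.00209) and 0.33 with it (SE 0.11, adjusted p = 0.0292). Tigar rose with PDGF-BB by 0.60 in wild-type (adjusted p = 0.000332) and by 0.41 in labelled knockout cells (adjusted p = 0.00789), and the interaction of -0.19 was not called (adjusted p = 0.520). The difference with PDGF-BB lost its call without replicate 2 of wild-type with PDGF-BB (0.31, adjusted p = 0.0724), without replicate 1 (0.35, adjusted p = 0.0551), 2 (0.35, adjusted p = 0.0598) or 3 (0.28, adjusted p = 0.107) of labelled knockout with PDGF-BB, and with no filter (0.33, adjusted p = 0.0560). Over all alternatives its adjusted p ran from 9.61e-06 to 0.107. The table holds 1 value per gene, so reads over single exons were not available, and every direction between genotypes given here is by label.

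**Figure D1:**
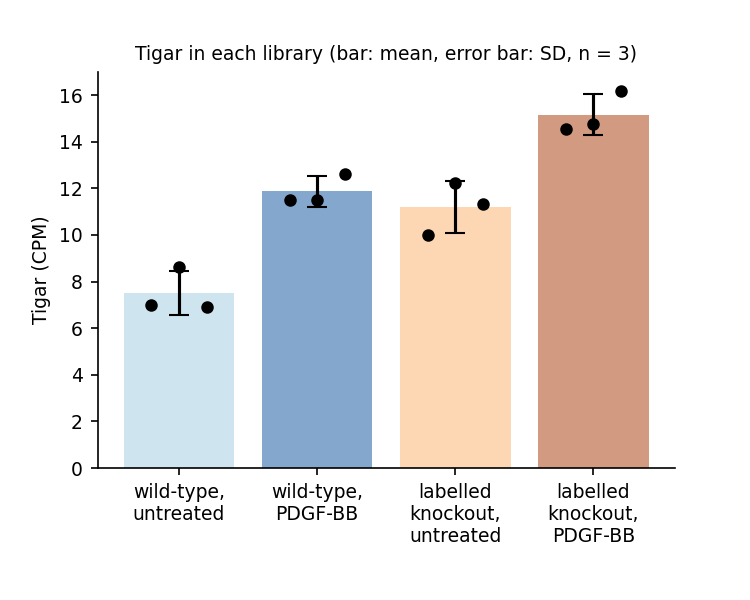
Tigar level in CPM (vertical axis, from 0) in each group, with bars for the mean, error bars for the SD and points for the 3 libraries. The groups labelled knockout stood at 11.2 and 15.2 CPM, above the wild-type groups of the same treatment at 7.50 and 11.9 CPM.

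The first comparison asked what 6 h of PDGF-BB did to wild-type cells. The largest rise was in Nptx1, a neuronal pentraxin (ENSMUSG00000025582, chromosome 11, 119538719 to 119547753), which went from 4.26 ± 0.209 to 129 ± 18.8 CPM (SD, n = 3), a log2 change of 4.62 (SE 0.13, adjusted p = 5.44e-11). Il1rl1, the receptor for interleukin 33, went from 0.781 ± 0.0764 to 39.8 ± 4.23 CPM, and Hk2, a hexokinase of the first step of glycolysis, from 5.65 ± 0.608 to 65.8 ± 1.95 CPM. The largest fall was in Edar, the ectodysplasin receptor (ENSMUSG00000003227, chromosome 10, 58600789 to 58675654), from 17.6 ± 0.398 to 0.820 ± 0.194 CPM (log2 -3.36, SE 0.12). Cyp26b1, which breaks down retinoic acid, went from 821 ± 12.1 to 122 ± 11.4 CPM.

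Further large rises on the log2 scale were in Il1rl1 (4.51), Crct1 (3.44), Ngef (3.37), Hk2 (3.33), Slurp1 (3.19), the AP-1 subunit Fosl1 (3.13), the G protein signalling regulator Rgs2 (3.13), the collagen gene Col15a1 (3.00), the cGMP-dependent kinase Prkg2 (2.96) and Bcat1 (2.94), an aminotransferase of branched-chain amino acids. Large falls were in Slc25a27 (-3.25), the Notch target Hey2 (-3.06), Klhl24 (-2.82), the mineralocorticoid receptor Nr3c2 (-2.79), Cyp26b1 (-2.74), Klf11 (-2.69), Hs6st1 (-2.65), Phactr1 (-2.60), the neuregulin gene Nrg1 (-2.53) and Coq8a (-2.51). The SE of these changes was at most 0.27, and the adjusted p at most 5.21e-07. In the annotation 57.2% of the exonic bases of Fosl1 lie in exons of Ccdc85b on the other strand, so its value depends on a strand setting that is not stated.

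Growth factor early genes rose as a group, with 23 of 29 measured members higher and 3 lower, and the same numbers adjusted over the list alone. Dusp5, a phosphatase of ERK, rose by 2.93 (SE 0.17), the EGF receptor ligand Hbegf by 2.76 (SE 0.12) and the urokinase receptor Plaur by 2.67 (SE 0.16). The median of the list was 1.45 (camera adjusted p = 3.96e-11), and adjusted p = 0.0219 with an estimated correlation kept the call. All 22 ribosome biogenesis genes rose, also adjusted over the list alone, among them Nop56 (1.92), Rrp12 (1.84) and the helicase Ddx21 (1.70). Their median was 1.19 (camera adjusted p = 1.23e-12), and adjusted p = 0.0718 with an estimated correlation.

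Metabolic lists rose too. In glycolysis 18 of 23 members rose and 2 fell, also adjusted over the list alone, with a median of 1.26 (camera adjusted p = 1.70e-09), and adjusted p = 0.0718 with an estimated correlation. The lactate exporter Slc16a3 rose by 2.58 (SE 0.12), the lactate dehydrogenase Ldha by 2.11 (SE 0.12) and the phosphofructokinase Pfkl by 1.75 (SE 0.084). In cholesterol synthesis 20 of 21 members rose, also adjusted over the list alone, with a median of 1.14 (camera adjusted p = 2.49e-10), and adjusted p = 0.392 with an estimated correlation. Idi1 and Cyp51 rose by 1.85 and 1.75. Of 22 ATF4 targets 17 rose and 2 fell, also adjusted over the list alone, with a median of 0.99 (camera adjusted p = 4.78e-06), and adjusted p = 0.459 with an estimated correlation. The mitochondrial folate enzyme Mthfd2 rose by 2.56 (SE 0.16) and the serine synthesis enzyme Psat1 by 1.89 (SE 0.15). Of 18 hypoxia targets 14 rose and 3 fell, also adjusted over the list alone, with a median of 0.84 (camera adjusted p = 2.39e-06), and adjusted p = 0.187 with an estimated correlation. Ak4 rose by 2.64 (SE 0.13), the clock repressor Bhlhe40 by 2.55 (SE 0.11) and the prolyl hydroxylase Egln3 by 2.01 (SE 0.11).

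Interferon-stimulated genes fell: 14 of 16 were lower, also adjusted over the list alone, with a median of -0.95 (camera adjusted p = 3.78e-05), and adjusted p = 0.459 with an estimated correlation. Ifit3 went from 28.7 ± 2.51 to 7.49 ± 2.20 CPM, and the RNA sensor Ifih1 from 21.5 ± 1.43 to 7.37 ± 0.496 CPM. Of 21 G2/M genes 16 fell, 17 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 0.00362), and adjusted p = 0.683 with an estimated correlation. The spindle checkpoint kinase Bub1b fell by 1.17 (SE 0.21), and the proliferation marker Mki67 went from 42.3 ± 12.9 to 19.7 ± 3.88 CPM. Over 22 other settings of filter, scaling, tool and left-out library, the adjusted p of these 8 lists stayed between 2.36e-24 and 0.0145. NRF2 targets (12 of 22 higher, 2 lower, also adjusted over the list alone, median 0.25, camera adjusted p = 0.0133, adjusted p = 0.600 with an estimated correlation) and respiratory chain genes (8 of 22 higher, 6 adjusted over the list alone, median 0.30, camera adjusted p = 0.00608, adjusted p = 0.699 with an estimated correlation) were called as well. Both calls ended without replicate 1 of wild-type with PDGF-BB, the library that stood apart, at adjusted p = 0.0989 and 0.135 and medians of 0.17 and 0.096, within ranges of 0.000377 to 0.121 and 0.000101 to 0.135 over the alternatives. With this library kept, the NRF2 call also ended at a mean CPM of at least 5 (0.0713) and under quantile normalization (0.0628).

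In the smooth muscle contractile list 8 of 18 members fell and 3 rose, 9 and 4 adjusted over the list alone, and camera did not call the list (median -0.28, adjusted p = 0.440). This median rested on single libraries: the list stood at 0.0016 in replicate 1 of wild-type with PDGF-BB, against -0.41 and -0.48 in replicates 2 and 3, and its median was -0.44 without replicate 1 and -0.18 without replicate 3. With 1 library left out its adjusted p stayed between 0.214 and 0.616. Myh11, the smooth muscle myosin heavy chain, went from 71.5 ± 6.36 to 35.9 ± 6.89 CPM, and Cald1 from 2532 ± 58.0 to 1326 ± 89.9 CPM. Matrix and synthetic-state genes went both ways, with 10 of 21 higher and 6 lower (7 adjusted over the list alone, adjusted p = 0.363), as in the proteoglycan Vcan (2.03, SE 0.18) and the transcription factor Klf5 (-1.58, SE 0.19). Of 7 PDGF ligands and receptors 4 fell, also adjusted over the list alone (adjusted p = 0.205), among them the receptor Pdgfra (-0.56, SE 0.15). Of 20 TGF-beta and YAP targets 13 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0616), with Tgfb2 at -1.54 and Tgfb1 at 0.94. Camera called this list lower without replicate 2 of wild-type untreated (adjusted p = 0.0473) or replicate 1 of wild-type with PDGF-BB (0.0117, the lowest with 1 library left out, up to 0.109). Of 16 matrix remodelling genes 8 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.140), with the inhibitor Timp1 at 2.62 and the aggrecanase Adamts5 at -2.17. Of 21 p53 targets 9 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.424), with Sesn1 at -1.60. Of 20 inflammatory genes 8 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.440), with Ptgs2, the inducible cyclooxygenase, at 1.72.

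Camera also left the following lists uncalled in this comparison, and their counts adjusted over all genes and adjusted over the list alone were alike. They were pentose phosphate and NADPH supply (7 of 13 higher, 2 lower, adjusted p = 0.0723), G1/S genes (9 of 22 higher, 4 lower, adjusted p = 0.363), osteochondrogenic genes (2 of 12 higher, 5 lower, adjusted p = 0.744), and autophagy and lysosome genes (3 of 20 higher, 8 lower, adjusted p = 0.499). Among marker lists, 5 of 10 endothelial (adjusted p = 0.205), 2 of 11 macrophage (adjusted p = 0.626) and 1 of 3 Schwann cell markers (adjusted p = 0.440) were lower. Of 10 fibroblast markers 3 were lower and 1 higher (adjusted p = 0.667).

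In all, limma-trend called 8431 of 14202 genes, 3547 higher and 4884 lower, of which 1411 changed at least 2-fold. The 3 against 3 libraries did not overlap for 62.3% of genes, against 10% by chance. With TMM scaling in the same test 4189 genes were called higher and 4175 lower, so the balance of rises and falls depends on the scaling. With edgeR on recovered reads, which also changes the model, 51.7% of the called genes were higher, against 42.1% in limma-trend. The median and the mean or camera's direction differed in sign for the inflammatory, Tigar neighbour and epithelial lists, and the inflammatory, macrophage, fibroblast and epithelial medians changed sign under quantile normalization.

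The second comparison asked the same question of the cells labelled knockout. Ngef, a guanine nucleotide exchange factor of the ephrin receptors (ENSMUSG00000026259, chromosome 1, 87476834 to 87573870), rose most, from 0.778 ± 0.150 to 30.8 ± 3.65 CPM (SD, n = 3, log2 4.16, SE 0.17, adjusted p = 4.79e-09). Il1rl1 went from 0.684 ± 0.224 to 25.2 ± 3.61 CPM, and Cd44, the hyaluronan receptor, from 99.5 ± 6.26 to 559 ± 52.6 CPM. Nog, which encodes the BMP antagonist noggin (ENSMUSG00000048616, chromosome 11, 89300638 to 89302332), fell most, from 9.97 ± 0.699 to 0.897 ± 0.0587 CPM (log2 -2.53, SE 0.12).

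Other large rises were in Il1rl1 (3.96), Crct1 (3.30), the endothelial lipase Lipg (2.78), Serpinb2 (2.75), Dusp5 (2.52), Fosl1 (2.49), Cd44 (2.47), the neuropeptide precursor Vgf (2.47), the retinaldehyde dehydrogenase Aldh1a3 (2.39) and Prkg2 (2.38). Other large falls were in Sost (-2.44), which encodes the Wnt antagonist sclerostin, Phactr1 (-2.40), Tent5c (-2.39), the FGF receptor Fgfr3 (-2.31), Cables1 (-2.15), Dlx6os1 (-2.13), Tppp (-2.13), the inhibin subunit Inhbb (-2.08), Mettl7a1 (-2.06) and the protease Adamts9 (-2.04). Their SE was at most 0.26 and their adjusted p at most 1.17e-05. As in wild-type cells, the value of Fosl1 rests on the strand setting.

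All 21 cholesterol synthesis genes rose, also adjusted over the list alone, with a median of 1.31 (camera adjusted p = 1.45e-16), and adjusted p = 0.184 with an estimated correlation. Hmgcs1 and Lss rose by 1.84 and 1.82. Of 29 early genes 24 rose and 2 fell, also adjusted over the list alone, with a median of 1.09 (camera adjusted p = 5.80e-14), and adjusted p = 0.0102 with an estimated correlation kept the call. Plaur rose by 2.10 (SE 0.16) and the EGF receptor ligand Ereg by 1.73 (SE 0.081). Of 22 ribosome biogenesis genes 21 rose, also adjusted over the list alone, with a median of 0.77 (camera adjusted p = 6.35e-14), and adjusted p = 0.0610 with an estimated correlation. Rrp12 rose by 1.34 and Nop56 by 1.31. In glycolysis 18 of 23 rose and 1 fell, also adjusted over the list alone, with a median of 0.70 (camera adjusted p = 2.02e-10), and adjusted p = 0.0610 with an estimated correlation. Hk2 went from 8.56 ± 0.575 to 36.6 ± 3.84 CPM. Of 18 hypoxia targets 12 rose and 3 fell, 13 and 3 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.000301), and adjusted p = 0.352 with an estimated correlation. Of 16 interferon-stimulated genes 12 fell, also adjusted over the list alone, with a median of -0.63 (camera adjusted p = 0.000941), and adjusted p = 0.559 with an estimated correlation. Usp18, which dampens interferon signalling, fell by 1.18 (SE 0.17). Over 22 other settings the adjusted p of these 6 lists stayed between 6.60e-28 and 0.00302.

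ATF4 targets went both ways, with 7 of 22 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.179), as in Psat1 (1.21) and Vldlr (-0.77). Of 18 contractile genes 4 rose and 6 fell, 5 and 6 adjusted over the list alone (adjusted p = 0.826), and the median of -0.05 became 0.0014 under TMM scaling. Of 12 osteochondrogenic genes 3 rose and 5 fell, 3 and 6 adjusted over the list alone (adjusted p = 0.706), among them Enpp1 (1.16) and the homeobox gene Msx2 (-0.93). In all, 6025 genes were called, 2502 higher and 3523 lower, of which 586 changed at least 2-fold, and the libraries did not overlap for 63.2% of genes, against 10% by chance. A fit of the compared groups alone gave 7896 calls here and 7114 in wild-type, so the order of these counts depends on the fit. With edgeR 49.9% of the called genes were higher, against 41.5% in limma-trend. The median and the mean or camera's direction differed in sign for contractile genes, p53 targets, G2/M, inflammatory, Tigar neighbour and epithelial lists, none of them called, and the inflammatory and Tigar neighbour medians changed sign under quantile normalization.

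The third comparison asked how untreated cells labelled knockout differed from wild-type ones. Angptl7, a secreted angiopoietin-like protein (ENSMUSG00000028989, chromosome 4, 148495183 to 148500460), fell from 1629 ± 48.2 CPM in wild-type to 38.4 ± 3.25 CPM in labelled knockout (SD, n = 3, log2 -5.37, SE 0.075, adjusted p = 2.20e-14). The cartilage matrix gene Comp fell from 292 ± 47.9 to 28.4 ± 6.25 CPM, and Nt5e, the ecto-enzyme that makes adenosine, from 76.0 ± 3.93 to 8.48 ± 0.264 CPM. Col15a1 (ENSMUSG00000028339, chromosome 4, 47208161 to 47313167) rose most, from 4.74 ± 0.791 to 59.2 ± 33.2 CPM (log2 3.27, SE 0.26). Acan, which encodes the cartilage proteoglycan aggrecan, rose from 79.9 ± 4.04 to 648 ± 35.8 CPM.

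Other large differences above wild-type were in the vascular phosphatase Ptprb (3.24), Sost (3.23), Acan (3.00), the endothelial sialomucin Emcn (2.93), Adgrf5 (2.92), Bmp6 (2.88), the Wnt antagonist Sfrp1 (2.88), Myct1 (2.83), Gdf6 (2.81) and the endothelial receptor Tie1 (2.80). Other large differences below wild-type were in Comp (-3.32), the ferritin receptor Scara5 (-3.25), the BMP antagonist Chrdl1 (-3.06), Nt5e (-3.02), Dlk1 (-2.79), C1qtnf3 (-2.54), Dio3os (-2.53), Dio3, which inactivates thyroid hormone (-2.51), Selenbp1 (-2.50), the Wnt agonist Rspo3 (-2.48) and Adamts5 (-2.40). Their SE was at most 0.26 and their adjusted p at most 6.59e-07.

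**Figure D2:**
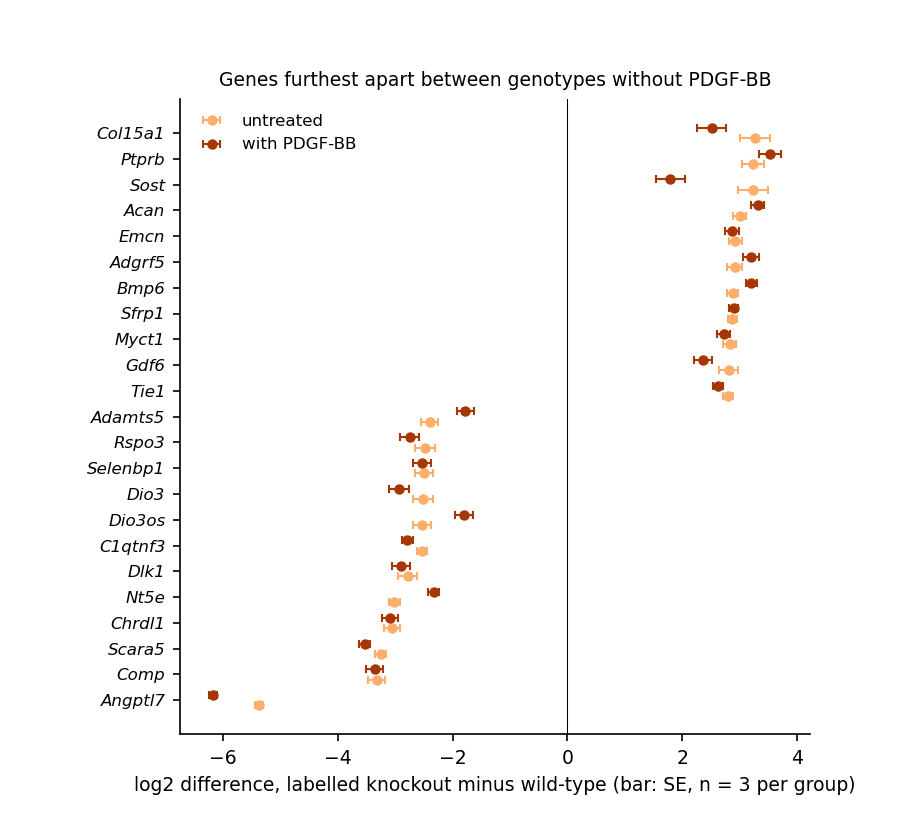
Log2 difference between labelled knockout and wild-type (horizontal axis) for the named genes, untreated (light) and with PDGF-BB (dark), with SE bars and 3 libraries per group. Angptl7 lay lowest in both states, at -5.37 and -6.18.

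Markers of other cell types moved with the genotype label. Of 10 endothelial markers 9 were higher, also adjusted over the list alone, with a median of 2.49 (camera adjusted p = 2.06e-17), and adjusted p = 0.00239 with an estimated correlation kept the call. The adhesion molecule Pecam1 rose from 37.8 ± 2.51 to 256 ± 7.87 CPM, and the endothelial cadherin Cdh5 from 27.3 ± 2.54 to 178 ± 15.0 CPM. All 11 macrophage markers were lower, also adjusted over the list alone, with a median of -1.16 (camera adjusted p = 7.36e-07), and adjusted p = 0.180 with an estimated correlation. Adgre1 went from 17.4 ± 1.78 to 2.56 ± 0.731 CPM and the lysozyme gene Lyz2 from 80.9 ± 4.43 to 18.5 ± 2.77 CPM. All 3 measured Schwann cell markers were lower, also adjusted over the list alone, with a median of -1.25 (camera adjusted p = 0.0253), and adjusted p = 0.181 with an estimated correlation. S100b went from 42.1 ± 4.06 to 13.4 ± 0.876 CPM. The list's call ended without replicate 1 of wild-type with PDGF-BB (adjusted p = 0.0508, the highest over the alternatives, from 0.00246). That library is not part of this comparison, and the median stayed at -1.25. Of 10 fibroblast markers 2 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.864), with Col14a1 at 2.57 and the actin-severing protein Gsn at -1.06. Of the 2 measured adipocyte markers, Fabp4 was higher (1.00, SE 0.24), and no list test was made. Of 3 epithelial markers 1 was higher and 1 lower, also adjusted over the list alone (adjusted p = 0.467), with Krt18 at 2.18. The 3 measured striated muscle markers had a median of -0.19 and were not called (adjusted p = 0.692).

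**Figure D3:**
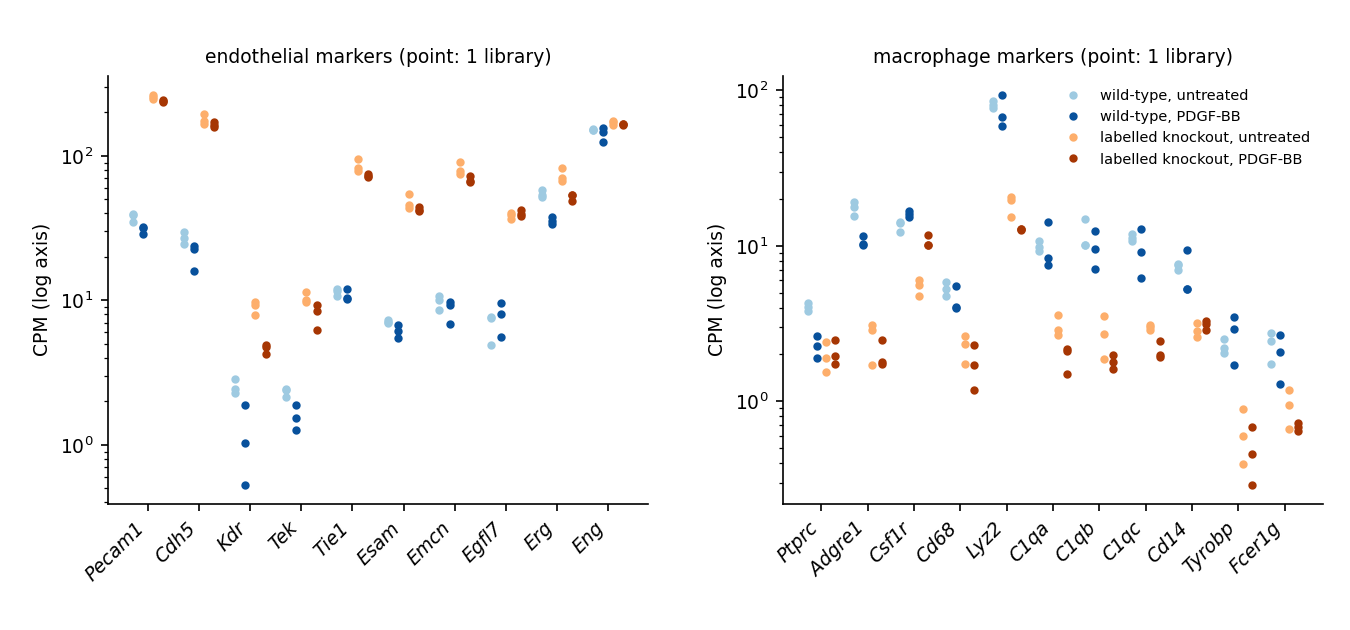
Level in CPM on a log axis of each endothelial marker (left) and macrophage marker (right) in each of the 12 libraries, coloured by group. Pecam1 stood at 256 CPM in labelled knockout untreated cells against 37.8 CPM in wild-type, and Lyz2 at 18.5 CPM against 80.9 CPM.

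Among smooth muscle lists, 10 of 18 contractile genes were higher, 11 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 5.93e-07), and adjusted p = 0.120 with an estimated correlation. Cnn1, the smooth muscle calponin, rose from 66.2 ± 11.3 to 147 ± 37.1 CPM, and Mcam from 36.9 ± 4.96 to 80.6 ± 4.83 CPM. Of 21 matrix and synthetic-state genes 12 were higher and 5 lower, 13 and 5 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.16e-05), and adjusted p = 0.0129 with an estimated correlation kept the call. Elastin (Eln) rose from 3747 ± 171 to 11670 ± 1645 CPM and the collagen gene Col1a1 from 1647 ± 45.1 to 4505 ± 231 CPM, while osteopontin (Spp1) fell by 2.11 (SE 0.17). Of 20 TGF-beta and YAP targets 14 were higher and 2 lower, also adjusted over the list alone, with a median of 0.49 (camera adjusted p = 4.57e-11), and adjusted p = 0.0136 with an estimated correlation kept the call. Tgfbi rose by 2.67 (SE 0.17), Ltbp2 by 1.89 (SE 0.13) and the YAP target Ankrd1 by 1.81 (SE 0.20). These lists and the endothelial and macrophage markers moved in the same libraries.

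All 21 G2/M genes were lower, also adjusted over the list alone, with a median of -1.17 (camera adjusted p = 9.85e-07), and adjusted p = 0.568 with an estimated correlation. The kinetochore gene Cenpf went from 26.7 ± 8.17 to 8.88 ± 3.54 CPM and the cyclin Ccnb1 from 19.8 ± 6.44 to 6.62 ± 2.56 CPM. Of 22 G1/S genes 5 were lower, also adjusted over the list alone (adjusted p = 0.609). ATF4 targets were higher in 12 of 22 members and lower in 3, 14 and 4 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 1.50e-06), and adjusted p = 0.457 with an estimated correlation. Trib3 rose by 1.54 (SE 0.15) and Mthfd2 by 1.32 (SE 0.16), while the lipoprotein receptor Vldlr fell by 1.69 (SE 0.099). Of 21 cholesterol synthesis genes 6 were higher, 5 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.000108), and adjusted p = 0.588 with an estimated correlation, as in Stard4 (0.62) and Sqle (0.51), and the median was 0.43 without replicate 1 and 0.16 without replicate 3 of labelled knockout untreated. Over 22 other settings the adjusted p of the lists named so far with a call, Schwann cells apart, stayed between 1.02e-56 and 0.0155. Fry, outside these settings, did not call cholesterol synthesis (adjusted p = 0.121). Of 20 inflammatory genes 8 were higher and 7 lower, 8 and 8 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.0113), and adjusted p = 0.483 with an estimated correlation. Il6 rose by 2.46 (SE 0.20) and the chemokine Cxcl12 from 1090 ± 40.0 to 2666 ± 164 CPM. The inflammatory median was 0.15 without replicate 3 of wild-type untreated or replicate 1 of labelled knockout untreated, and the call ended under TMM scaling (adjusted p = 0.0883) and quantile normalization (adjusted p = 0.0708), within a range of 0.00320 to 0.174.

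Of 12 osteochondrogenic genes 4 were higher and 6 lower, also adjusted over the list alone (adjusted p = 0.613), with Acan and Comp at the extremes. PDGF ligands and receptors were not called as a list (median -0.15, camera adjusted p = 0.392). In this list 2 of 7 members were higher and 1 lower, also adjusted over the list alone. The ligand gene Pdgfb rose from 6.15 ± 0.867 to 29.3 ± 4.26 CPM. Of 14 measured genes near Tigar on the chromosome 2 were higher and 4 lower, 2 and 5 adjusted over the list alone (adjusted p = 0.808), among them Vwf (2.64), an endothelial clotting factor gene. Of 4 measured sex-linked genes, all on the Y chromosome, 1 was lower, 2 adjusted over the list alone (adjusted p = 0.864). In all, 4823 genes were called, 1300 higher and 3523 lower, of which 747 differed at least 2-fold, and the libraries did not overlap for 54.7% of genes, against 10% by chance. TMM scaling moved the median of all genes from -0.13 to -0.0071 and gave 3967 calls, 1931 higher and 2036 lower, so the excess of lower genes is relative to the scaling. Of the 4823 genes 3336 kept their call under it, array weights raised the count to 8006, and the medians of pentose phosphate, p53, ribosome biogenesis, matrix remodelling and respiratory chain genes, none called, changed sign under TMM scaling. The median, mean and test differed in sign for these lists apart from p53, and for the PDGF, osteochondrogenic, Tigar neighbour, fibroblast, epithelial and striated muscle lists.

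The fourth comparison asked how the cells labelled knockout differed from wild-type ones after PDGF-BB. Angptl7 again differed most, at 15.4 ± 1.25 CPM against 1185 ± 42.6 CPM (SD, n = 3, log2 -6.18, SE 0.075, adjusted p = 3.49e-15). Ptprb (ENSMUSG00000020154, chromosome 10, 116275523 to 116389535) stood highest above wild-type, at 154 ± 1.86 CPM against 13.0 ± 4.76 CPM (log2 3.53, SE 0.20). Edn1, which encodes the vasoconstrictor endothelin, stood at 76.6 ± 2.44 CPM against 7.12 ± 0.960 CPM. Rgs2 stood at 19.4 ± 1.08 CPM against 159 ± 48.2 CPM, and Adcyap1r1, a neuropeptide receptor, at 62.0 ± 3.00 CPM against 392 ± 46.5 CPM.

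Other genes far above wild-type were Acan (3.32), Bmp6 (3.20), Adgrf5 (3.20), Cdh5 (2.95), Pecam1 (2.92), Ctla2a (2.92), Sfrp1 (2.90), the endothelial lectin Cd93 (2.89) and Emcn (2.87). Far below were Scara5 (-3.53), Comp (-3.36), Chrdl1 (-3.09), Dio3 (-2.94), Rgs2 (-2.93), Dlk1 (-2.90), C1qtnf3 (-2.79), Rspo3 (-2.75), Adcyap1r1 (-2.64), Enpp2 (-2.59), which makes lysophosphatidic acid, and Selenbp1 (-2.54). Their SE was at most 0.26 and their adjusted p at most 4.12e-06.

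Most lists called in the untreated comparison were called again, and 3 were not. ATF4 targets, higher without PDGF-BB, had 2 of 22 members higher and 11 lower, 3 and 14 adjusted over the list alone, with a median of -0.36 (adjusted p = 0.0746). Of 21 G2/M genes 2 were lower by limma-trend, but 0 adjusted over the list alone, with 4 at unadjusted p under 0.05, 1 called by edgeR and 1 by DESeq2 (median -0.37, adjusted p = 0.298). Of 3 Schwann cell markers 2 were lower, also adjusted over the list alone (adjusted p = 0.230).

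All 10 endothelial markers were higher, also adjusted over the list alone, with a median of 2.44 (camera adjusted p = 5.27e-17), and adjusted p = 0.00260 with an estimated correlation kept the call. Of 11 macrophage markers 10 were lower, also adjusted over the list alone, with a median of -1.30 (camera adjusted p = 9.06e-06), and adjusted p = 0.202 with an estimated correlation. In the same libraries 14 of 18 contractile genes were higher, 16 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 5.44e-11), and adjusted p = 0.0356 with an estimated correlation kept the call. Lmod1, which nucleates actin, stood at 164 ± 3.42 CPM against 80.4 ± 6.82 CPM, and the myosin light chain kinase Mylk at 28.6 ± 1.84 CPM against 13.6 ± 3.47 CPM. TGF-beta and YAP targets (14 of 20 higher, 1 lower, also adjusted over the list alone, median 0.64, camera adjusted p = 1.32e-12, adjusted p = 0.00896 with an estimated correlation) and matrix genes (10 of 21 higher, 4 lower, also adjusted over the list alone, median 0.38, camera adjusted p = 5.03e-06, adjusted p = 0.00896 with an estimated correlation) were again called higher. Cholesterol synthesis was higher in 12 of 21 members, 13 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 7.60e-08), and adjusted p = 0.347 with an estimated correlation, as in Stard4 (0.63) and Sqle (0.58). Of 20 inflammatory genes 7 were higher and 5 lower, 9 and 6 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.00749), and adjusted p = 0.354 with an estimated correlation, as in Il6 (2.26) and Icam1 (1.16).

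Glycolysis, hypoxia targets and ribosome biogenesis, which PDGF-BB raised in both genotypes, stood lower in labelled knockout after treatment, while early genes were not called (5 of 29 higher, 13 lower, also adjusted over the list alone, median -0.20, adjusted p = 0.391). In glycolysis 19 of 23 members were lower, also adjusted over the list alone, with a median of -0.54 (camera adjusted p = 2.19e-06), and adjusted p = 0.120 with an estimated correlation. Slc16a3 stood at 25.1 ± 1.35 CPM against 61.0 ± 7.47 CPM and Pfkl at 142 ± 1.10 CPM against 288 ± 41.5 CPM. Of 18 hypoxia targets 16 were lower and 1 higher, also adjusted over the list alone, with a median of -0.59 (camera adjusted p = 1.75e-05), and adjusted p = 0.189 with an estimated correlation. Bnip3, which directs mitochondria to autophagy, stood at 20.4 ± 0.670 CPM against 52.5 ± 9.10 CPM, and Pdk1 at 39.2 ± 3.66 CPM against 89.0 ± 6.94 CPM. Of 22 ribosome biogenesis genes 17 were lower, 20 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.000245), and adjusted p = 0.347 with an estimated correlation, as in Fbl (-0.73) and Nop58 (-0.53). Over 22 other settings the adjusted p of the 10 lists called in this comparison stayed between 1.14e-54 and 0.0263. The wild-type library that stood apart belongs to this comparison, and log2 differences rose with exon length across genes (Spearman rho 0.26). In all, 5284 genes were called, 1507 higher and 3777 lower, of which 671 differed at least 2-fold, and the libraries did not overlap for 49.5% of genes, against 10% by chance. TMM scaling gave 1924 higher and 2155 lower of 4079 calls, array weights gave 10265 calls, and a fit of these 2 groups alone gave 3438. The median, mean and test differed in sign for the PDGF, p53, osteochondrogenic, Tigar neighbour and epithelial lists, none called, and scaling turned the sign of the PDGF and p53 medians (TMM) and of the sex-linked one (quantile).

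The differences between genotype labels without and with PDGF-BB overlapped: 908 genes were higher in both states, against 138 if the calls were independent, and 1972 were lower in both, against 937. In 75 genes the calls went in opposite directions. Across 14202 genes the log2 differences of both states correlated at Pearson r 0.770 and Spearman rho 0.561, with genes not being independent replicates. PDGF-BB responses likewise correlated between genotypes at r 0.871 and rho 0.856, and 2185 genes rose in both, against 625 if independent, and 3062 fell in both, against 1212. With edgeR on recovered reads the r of the responses was 0.82 with its filter on low counts and 0.257 without it. This pair differs in the filter alone, so the drop in edgeR goes with the genes that the filter removes. With DESeq2, also run without that filter, r was 0.342, and the cause there was not tested.

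The last comparison asked whether the response to PDGF-BB differed between the genotypes. Nptx1 rose from 7.65 ± 1.39 to 31.2 ± 2.46 CPM in labelled knockout, against 4.26 ± 0.209 to 129 ± 18.8 CPM in wild-type (SD, n = 3), an interaction of -2.72 (SE 0.18, adjusted p = 1.35e-05). Rgs2 rose from 7.30 ± 0.0393 to 19.4 ± 1.08 CPM in labelled knockout and from 16.7 ± 0.545 to 159 ± 48.2 CPM in wild-type (interaction -1.84, SE 0.21). Mthfd2 had an interaction of -1.96 (SE 0.22). Among positive interactions that kept their call in every alternative run, the largest were in Nr3c2 (1.77, SE 0.24), the Wnt antagonist Dkk2 (1.73, SE 0.17), Nrg1 (1.69, SE 0.19), the TNF family ligand Tnfsf15 (1.68, SE 0.17) and Rassf4 (1.61, SE 0.24). Dkk2 went from 6.44 ± 0.286 to 3.85 ± 0.181 CPM in wild-type and from 5.86 ± 0.538 to 13.9 ± 2.08 CPM in labelled knockout.

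**Figure D4:**
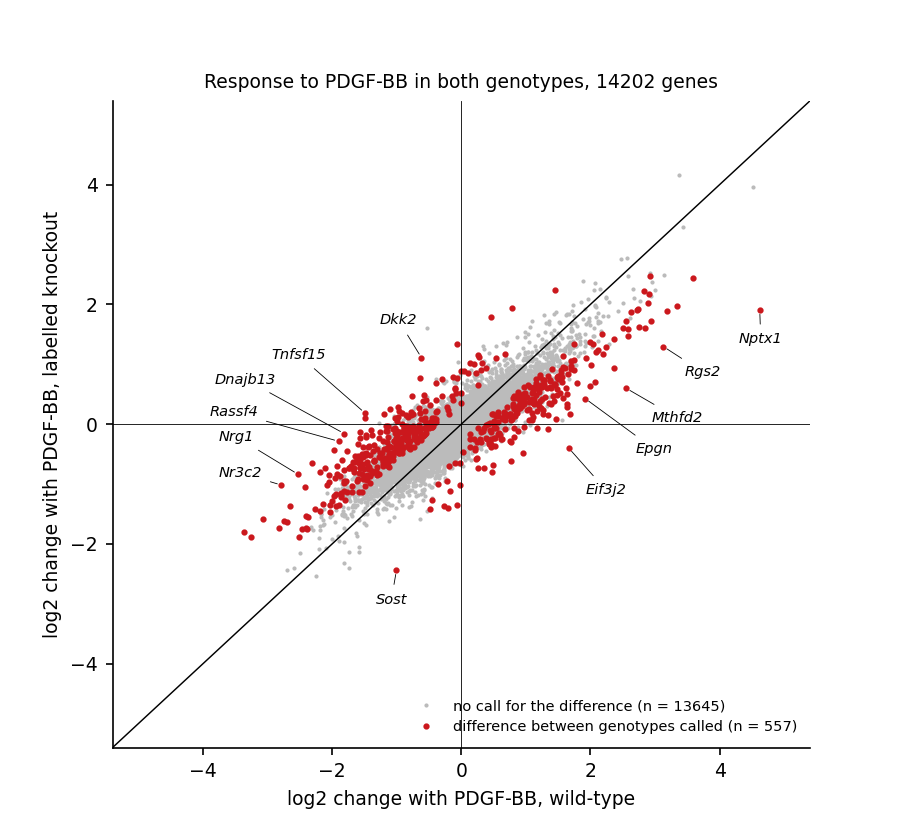
Log2 change with PDGF-BB in wild-type (horizontal axis) and labelled knockout (vertical axis) for 14202 genes, with the 557 genes called for the interaction in red and the line of equal change. Nptx1 lies far below the line, at 4.62 and 1.90.

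The response was smaller in labelled knockout for most genes. Over the 9331 genes called in the mean effect of both genotypes, the median response was 0.55 in wild-type and 0.39 in labelled knockout, with a median difference of -0.17, and 76.5% of the genes had the smaller response in labelled knockout. The median response of single libraries was 0.64, 0.52 and 0.50 in wild-type and 0.39, 0.37 and 0.40 in labelled knockout. Of the 557 genes called for the interaction, 135 rose and 176 fell in both genotypes with the smaller change in labelled knockout. In 16 genes a rise in wild-type met a fall in labelled knockout, and in 14 genes the reverse held.

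Of the lists that PDGF-BB raised in wild-type cells, ATF4 targets, glycolysis, hypoxia targets, early genes and ribosome biogenesis had negative interactions. ATF4 targets had a median of -0.73, with 9 of 22 members negative, 16 and 1 positive adjusted over the list alone (camera adjusted p = 1.50e-13), and adjusted p = 0.164 with an estimated correlation. Trib3 (-1.43), the asparagine synthetase Asns (-1.31) and Aars (-1.03) are examples. Glycolysis had a median of -0.41, with 10 of 23 members negative and 1 positive, 15 and 1 adjusted over the list alone (camera adjusted p = 1.00e-08), and adjusted p = 0.0832 with an estimated correlation. Hk2 (-1.36, SE 0.14) and Pfkfb3 (-1.14, SE 0.17), an activator of glycolysis, are examples. Hypoxia targets had a median of -0.57, with 8 of 18 members negative, 11 and 1 positive adjusted over the list alone (camera adjusted p = 1.40e-09), and adjusted p = 0.0832 with an estimated correlation, as in Egln3 (-1.02). Early genes had a median of -0.34, with 4 of 29 members negative and 1 positive, 11 and 2 adjusted over the list alone (camera adjusted p = 4.13e-06), and adjusted p = 0.0832 with an estimated correlation, as in Hbegf (-1.13), Jun (-1.11) and Egr3 (-1.02). Ribosome biogenesis had a median of -0.36, with Ddx21 (-0.65) the 1 negative member and 14 adjusted over the list alone (camera adjusted p = 8.09e-08), and adjusted p = 0.164 with an estimated correlation. Called genes at large also responded less in labelled knockout (median 0.39 against 0.55). Such shrinkage alone makes the interaction negative for lists that rose and positive for lists that fell. The ratio of responses, labelled knockout to wild-type, was 0.75 for early genes and 0.72 for ribosome biogenesis. It was 0.69 for interferon-stimulated genes, 0.62 for glycolysis and 0.44 for hypoxia targets. Whether any list shrank more than called genes at large was not tested.

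G2/M and interferon-stimulated genes, which PDGF-BB lowered in wild-type cells, had positive interactions. Of 21 G2/M genes limma-trend called 0 over all genes, with 14 positive at unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2. Their median was 0.79, and 0.51 without replicate 1 of labelled knockout untreated, with 11 of 21 members positive adjusted over the list alone (camera adjusted p = 5.01e-08), and adjusted p = 0.592 with an estimated correlation. Interferon-stimulated genes had a median of 0.42, with 2 of 16 members positive, 6 adjusted over the list alone (camera adjusted p = 0.000267), and adjusted p = 0.592 with an estimated correlation, as in Ifit2 (0.97, SE 0.12), and without that library the median was 0.69. The adjusted p of these 7 lists stayed between 8.12e-22 and 0.00399 over 22 other settings. Fry, outside these settings, ended the calls of G2/M genes (adjusted p = 0.167) and interferon-stimulated genes (0.126). Cholesterol synthesis was not called (median 0.14, adjusted p = 0.0894), though it was without replicate 1 of wild-type with PDGF-BB (median 0.19, adjusted p = 0.0280) or replicate 2 (0.23, 0.00525) or 3 (0.23, 0.00349) of labelled knockout untreated, within a range of 0.00349 to 0.830 over left-out libraries.

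**Figure D5:**
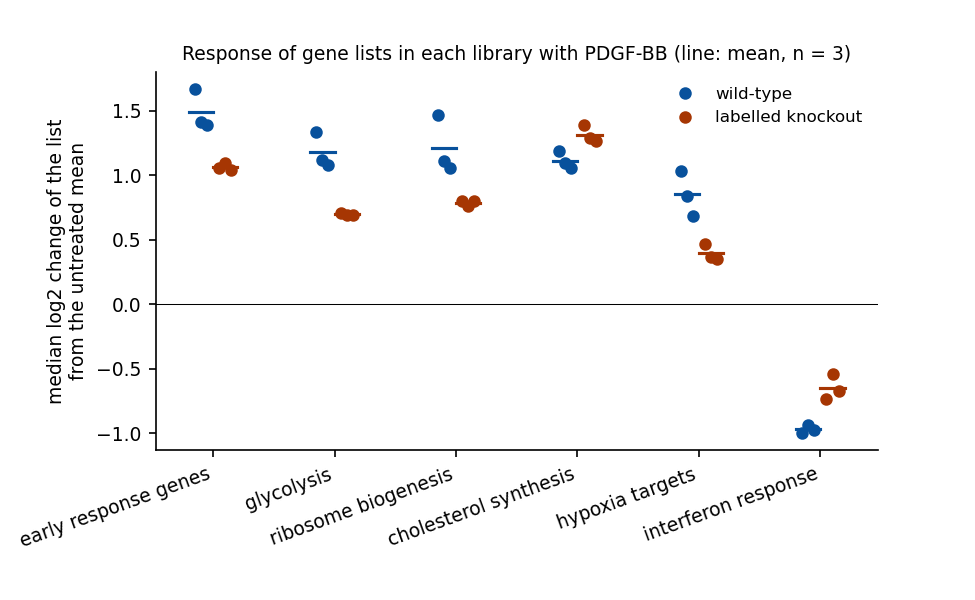
Median log2 change of each list from the untreated mean (vertical axis) in each library with PDGF-BB, for the 6 lists called in both genotypes, with a line for the mean of 3 libraries. Cholesterol synthesis alone of these 6 lay further from 0 in every labelled knockout library than in any wild-type one, with a ratio of 1.17 between the medians, against 0.440 for hypoxia targets.

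Contractile genes, p53 targets, NRF2 targets and respiratory chain genes were also called, but each call ended without 1 or more libraries. Fry ended the contractile (adjusted p = 0.261), NRF2 (0.261) and respiratory chain calls (0.326). The contractile list (median 0.22, camera adjusted p = 0.0321, adjusted p = 0.626 with an estimated correlation, 2 of 18 members positive, also adjusted over the list alone) lost its call without replicate 2 of wild-type untreated (adjusted p = 0.144), 3 of wild-type with PDGF-BB (0.0769) or 1 of labelled knockout untreated (0.222), within a range of 0.00636 to 0.222. The p53 list (median 0.11, camera adjusted p = 0.0331, adjusted p = 0.313 with an estimated correlation, 2 of 21 members positive, 5 adjusted over the list alone) lost it without replicate 2 of wild-type untreated (0.109), 2 (0.0624) or 3 (0.143) of wild-type with PDGF-BB, 1 of labelled knockout untreated (0.120) or 2 of labelled knockout with PDGF-BB (0.0546, median 0.073), within a range of 0.00176 to 0.143. NRF2 targets (median -0.23, camera adjusted p = 0.00518, adjusted p = 0.646 with an estimated correlation, 0 of 22 members called by limma-trend over all genes, 7 negative at unadjusted p under 0.05, 3 called by edgeR and 4 by DESeq2, 4 negative adjusted over the list alone) and respiratory chain genes (median -0.22, camera adjusted p = 0.000340, adjusted p = 0.705 with an estimated correlation, 1 of 22 members negative, 2 adjusted over the list alone) lost it without replicate 1 of wild-type with PDGF-BB, at 0.194 and 0.140 and medians of -0.026 and -0.035, within ranges of 0.000404 to 0.204 and 2.48e-06 to 0.140.

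In all, limma-trend called 557 of 14202 genes for the interaction, 319 positive and 238 negative, of which 120 were at least 2-fold. Single libraries moved this count: it was 1548 without replicate 1 and 894 without replicate 3 of wild-type with PDGF-BB, 273, 345 and 311 without replicates 1, 2 and 3 of wild-type untreated, 335 and 326 without replicates 2 and 3 of labelled knockout untreated, and 282, 272 and 309 without replicates 1, 2 and 3 of labelled knockout with PDGF-BB. Without replicate 1 of wild-type with PDGF-BB 550 of the 557 genes kept their call. The share of positive interactions was 57.3% and dropped to 46.5% under TMM scaling, 44.3% with edgeR and 44.6% with DESeq2, so neither sign can be said to prevail. Interactions rose with exon length across genes (Spearman rho 0.29). The matrix and TGF-beta medians, near 0 and not called, changed sign under TMM scaling, the endothelial one under quantile normalization and the sex-linked one under TMM scaling, and the median, mean and test differed in sign for the inflammatory, Tigar neighbour, macrophage, epithelial and sex-linked lists.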

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

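The tests of the library standing apart, of the exon length trend, of the share of responding cells, of the share of smooth muscle cells and of both Tigar explanations were chosen only after the results were seen, as was the removal of the exon length trend.

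The response to PDGF-BB differed between the genotypes by the interaction test, which limma-trend called for 557 genes. By camera it was called for ATF4 targets (median -0.73), hypoxia targets (-0.57), glycolysis (-0.41), ribosome biogenesis (-0.36), early genes (-0.34), NRF2 targets (-0.23), respiratory chain genes (-0.22), G2/M genes (0.79), interferon-stimulated genes (0.42), contractile genes (0.22) and p53 targets (0.11). None of these 11 lists kept the call with an estimated correlation. A smaller response of most genes in labelled knockout could alone give these signs for lists that PDGF-BB moved. The lists were not tested against such a general shrinkage. Fry called 6 of 29 lists for the interaction, and not the G2/M, interferon, contractile, NRF2 and respiratory chain lists. Without replicate 1 of wild-type with PDGF-BB the NRF2 and respiratory chain medians were -0.026 and -0.035 and both calls ended (adjusted p = 0.194 and 0.140, within ranges of 0.000404 to 0.204 and 2.48e-06 to 0.140). Genes with the largest interactions were Nr3c2 (1.77), Dkk2 (1.73), Nrg1 (1.69), Tnfsf15 (1.68), Dnajb13 (1.66), Rassf4 (1.61), Nptx1 (-2.72), Eif3j2 (-2.07), Mthfd2 (-1.96), Rgs2 (-1.84), Epgn (-1.49) and Sost (-1.44).

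Among these 12 genes 4 lost the call in some alternatives. Sost lost it with no filter and with the replicate block at an unchanged value, and its value shrank with a pseudocount of 0.1 (-0.80), with edgeR (-0.81, without a filter -0.79) and with DESeq2 (-0.78), which also ended the call. It lost it too without replicate 1 (adjusted p = 0.116), 2 (0.0882) or 3 (0.0913) of wild-type untreated, 2 of wild-type with PDGF-BB (0.0744), 2 of labelled knockout untreated (0.0668) or 1 (0.101), 2 (0.125) or 3 (0.0678) of labelled knockout with PDGF-BB, over a range of 0.000125 to 0.575. Eif3j2 lost it with no filter (0.0907) and without replicate 1 (0.0841) or 3 (0.0863) of wild-type untreated, 2 (0.0824) or 3 (0.0677) of labelled knockout untreated, or 1 (0.0701) or 2 (0.0821) of labelled knockout with PDGF-BB, over a range of 9.24e-13 to 0.0907, and its reads may be shared with its paralog Eif3j1, which was not tested. Epgn lost it with edgeR (0.116, without a filter 0.0869) and DESeq2 (0.0769), over a range of 8.83e-07 to 0.116. Dnajb13 lost it with edgeR (0.0710, the highest over a range from 2.15e-07) and had no adjusted p with DESeq2.

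The smaller response to PDGF-BB in the libraries labelled knockout (median difference -0.17) was weighed against 3 explanations. Without replicate 1 of wild-type with PDGF-BB the median difference stayed at -0.11, and with the trend with exon length removed at -0.15, each below 0 by more than the pooled SD of the library responses of 0.0568, so neither accounts for all of it. A smaller share of responding cells was predicted to shrink each list by a like ratio below 1. The ratio of the responses was 1.17 for cholesterol synthesis and 0.440 for hypoxia targets. Log2 changes need not scale with the share of responding cells, and markers of other cell types differed between the labels. Unlike ratios therefore cannot decide on this explanation. With any 1 of the 12 libraries left out the cholesterol ratio ran from 1.05 to 1.27. The ratios of the other 5 lists called in both genotypes ran from 0.394 to 0.781, below the cholesterol range. These ranges come from overlapping sets of libraries and are not standard errors. The larger cholesterol response itself is not established: its interaction was not called (median 0.14, adjusted p = 0.0894, from 0.00349 to 0.830 over left-out libraries), and without replicate 1 of labelled knockout untreated the libraries of both genotypes overlapped. A genotype difference remains a candidate explanation, as does a smaller share of responding cells. Differences between the animals or cultures, which the labels do not separate from genotype, remain candidates too.

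Endothelial markers were higher and macrophage markers lower in the libraries labelled knockout. A lower share of smooth muscle cells that raised all other cell types alike would raise both. The macrophage median was -1.16 (SE over members 0.162) while the endothelial one was 2.49 (SE 0.319), with members not being independent replicates. These values do not speak to a lower share made up by endothelial cells alone. Of 15 measured endothelial genes outside the marker list 14 were higher and 1 lower without PDGF-BB (median 1.52). Of 15 measured macrophage genes outside the marker list 14 were lower (median -1.11). Cultures with more endothelial cells and fewer macrophages may therefore account for the pattern. Both further lists were written after the marker pattern had been seen, so their members may include genes already seen. The most abundant markers were Pecam1, at 256 CPM against 37.8 CPM, and Lyz2, at 18.5 CPM against 80.9 CPM, and the labels name no sort that would remove either cell type. Expression of these genes by the smooth muscle cells themselves was not tested and stays open.

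Tigar was not lower in the libraries labelled knockout. An exchange of all genotype labels, with an allele that gives no Tigar reads, is excluded by the lowest count in a library labelled wild-type, 111 reads. An allele that still gives Tigar reads may account for the pattern, but the log2 difference of 0.52 covers the whole gene, and it cannot be told apart from other causes without values per exon. No test here shows that Tigar was lost in any library.

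For each comparison 6 libraries of 3 against 3 make only 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count in each. For the interaction, fitted on all 12 libraries, only the 6 with PDGF-BB were split, after removal of the additive effects of genotype and treatment. With limma the real counts were 8431 and 6025 for PDGF-BB in wild-type and labelled knockout, 4823 and 5284 for the genotype without and with PDGF-BB, and 557 for the interaction, against 0 as the highest of the other splits. At an unadjusted p under 0.05 the real counts were 9009, 7126, 6193, 6736 and 2730, and the highest others 1229, 264, 653, 1019 and 2406. In any other split the real effect enters the spread within the mixed groups, which by itself holds down the calls. The gap between real and other counts therefore does not measure chance. These splits were not run with another tool.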

How the results depend on the processing

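The removal of the exon length trend, over all libraries, within groups or with replicate 1 of wild-type with PDGF-BB left out, was chosen only after the results were seen. No call of a gene or list turned to the opposite direction, but the balance of calls did. The interaction had 319 positive and 238 negative calls, against 261 and 300 with TMM scaling, and PDGF-BB in wild-type 3547 higher and 4884 lower, against 4189 and 4175. The genotype untreated had 1300 higher and 3523 lower, against 2140 and 1828 with DESeq2, and with PDGF-BB 1507 and 3777, against 2132 and 1948. Of the alternative values, 1060 for gene lists and 13555 for named genes stayed on the same side of the threshold with the same direction, and 67 and 625 lost the call. With a change of at least 2-fold required, the 5 counts were 1411, 586, 747, 671 and 120, by construction. Array weights gave 8006 genes for the genotype untreated, 10265 with PDGF-BB and 4720 for the interaction. A fit of the compared groups alone gave 7114 for PDGF-BB in wild-type and 7896 in labelled knockout. It gave 6453 for the genotype untreated and 3438 with PDGF-BB. In the fit of all groups both orders were the reverse, so which contrast has more calls depends on the fit. The interaction count was 371 with no filter, 228 with a replicate block, 948 with edgeR without a filter, 847 with DESeq2, 1132 with the length trend removed, 1601 with it removed within groups, and 1715 with it removed and the library left out. Leaving out 1 library at a time gave interaction counts of 272 to 1548. Without replicate 1 of wild-type with PDGF-BB the genotype untreated had 7098 calls and PDGF-BB in labelled knockout 8065. That library is in neither contrast, but it enters the shared fit. The r of the PDGF-BB responses was 0.82 with edgeR, 0.26 with edgeR without a filter and 0.34 with DESeq2. Tigar with PDGF-BB (0.33) lost its call with no filter, and lay between 0.28 and 0.37 with 1 library left out. Camera called 47 list tests, and 9 with an estimated correlation. Fry called 81, among them 41 of the 47. With 1 library left out, lists without a call gained one in 1 to 3 of the 12 cases: beside those in the report, ATF4 targets, respiratory chain genes, interferon-stimulated genes and p53 targets for the genotype with PDGF-BB, interferon-stimulated genes, NRF2 targets and early genes for the genotype untreated, TGF-beta and YAP targets and G1/S genes for PDGF-BB in labelled knockout, pentose phosphate genes for PDGF-BB in wild-type, and these and TGF-beta and YAP targets for the interaction. The response size difference lay between -0.22 and -0.11 throughout. Except for the 2-fold requirement and the drop in r without the edgeR filter, the cause of these shifts was not tested. Whether the numbers in the sample names pair libraries is not known. Deviations of same-number libraries correlated across genes at -0.23, -0.21 and 0.15 in wild-type and 0.0098, -0.057 and 0.040 in labelled knockout. Deviations from a mean of 3 libraries constrain each other. Replicate 1 of wild-type with PDGF-BB also carried a trend with exon length. These correlations therefore cannot decide whether the block measures a pairing. At the lowest depth, 1 read was 0.0669 CPM, which limits genes near 1 CPM.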

Other observations

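The lists in this part were written after changes of single genes had been seen, and before the results of the lists were computed.

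FoxO target genes fell with PDGF-BB in both genotypes: 14 of 15 measured members in wild-type (median -1.06, camera adjusted p = 8.17e-08, adjusted p = 0.0182 with an estimated correlation) and 12 of 15 in labelled knockout (median -0.92, camera adjusted p = 1.01e-07, adjusted p = 0.0189 with an estimated correlation). Fbxo32, a ubiquitin ligase of muscle atrophy, fell by 2.14 in wild-type and by 1.33 in labelled knockout, the insulin receptor substrate Irs2 by 2.33 and 1.72, and Pdk4, which restrains pyruvate oxidation, by 1.93 and 1.36. The interaction was positive, with 3 of 15 members called (median 0.43, camera adjusted p = 1.36e-05, adjusted p = 0.0493 with an estimated correlation). Without PDGF-BB the list stood lower in labelled knockout than in wild-type, with 7 members lower and 1 higher (median -0.31, camera adjusted p = 0.0160). With an estimated correlation that call ended (adjusted p = 0.145). With PDGF-BB the genotype difference was not called (median 0.067, camera adjusted p = 0.326). The values of Fbxo32, Irs2, Klf15, Txnip and Cdkn1b had been seen before the list was written. Of the other 10 members 9 were lower in wild-type (median -0.92, adjusted p = 2.82e-05, and 0.00313 with an estimated correlation) and 8 in labelled knockout (median -0.65, adjusted p = 2.74e-05, and 0.00313), in a camera test added after the results were seen. Their interaction stayed positive (median 0.22, adjusted p = 0.00258, and 0.0137), with 1 of 10 members called. FoxO activity was not tested.

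Circadian clock genes were tested for a joint fall and were not called: 9 of 14 were lower and 3 higher in wild-type (median -0.57, camera adjusted p = 0.149), and 6 lower and 3 higher in labelled knockout (median -0.21, camera adjusted p = 0.458). Their interaction was called, with 5 of 14 positive (median 0.34, camera adjusted p = 0.00812), but not with an estimated correlation (adjusted p = 0.297). The output gene Dbp fell by 2.27 and 1.42, and the activator Arntl rose by 1.60 and 1.01.

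All 7 measured genes of the imprinted Dlk1-Dio3 cluster were lower in the libraries labelled knockout, with a median of -1.22 without PDGF-BB and -1.53 with it. Dlk1, Dio3 and Dio3os had been seen before. The other 4 genes were Meg3 (-1.22 without and -0.92 with PDGF-BB), Rian (-0.99 and -0.98), Mirg (-1.13 and -1.53) and Rtl1 (-0.93 and -1.11), and the higher of their medians of both states was -1.04. A camera test of these 4 alone, added after the results were seen, gave adjusted p = 0.000170 in each state, and 0.0115 with an estimated correlation. Imprinted genes of other clusters were not called as a list, with 7 of 12 lower and 1 higher without PDGF-BB (adjusted p = 0.242) and 7 lower and 2 higher with it (adjusted p = 0.959), with Peg10 at 2.14 and Mest at -1.02 without it. Over all 14202 genes 3523 were called lower without PDGF-BB and 3777 with it. The missing list call does not show that other imprinted genes were unchanged. A change in the cluster as a whole may underlie the fall. Markers of other cell types also differed between the labels. Neither a different mix of cells nor a difference between the animals was tested for these genes.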
